A study of Mus musculus with 16 samples.

How the data were processed

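RNA was measured in 16 libraries of mouse neural tube organoids on day 4, made from the R1 embryonic stem cell line carrying a FOXA2-Venus reporter and treated with retinoic acid for 18 hours. BRB-seq is a bulk 3′ RNA-seq method in which samples are barcoded and pooled early, so most reads come from the end of the transcript. Cells fell into 4 groups by FOXA2 level (negative, low, medium and high), with 4 libraries each. The labels number the libraries of each group but do not say that the numbers stand for separate cultures, so p-values measure the spread between these libraries, which may be partly technical.

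The authors deposited a single table of raw counts, whole numbers for 35976 genes in 16 columns, with no normalization. The submitters' processing notes name cutadapt 1.18, STARsolo 2.7.9a, DESeq2 1.42.0 and the genome build GRCm38, with no parameters. The gene annotation, the strand setting and whether reads were collapsed by molecular identifier are not given in the sources used here. Columns were matched to samples by name. Of the gene symbols, 26763 were found in GENCODE M21, which uses the same build and supplied the coordinates given here, and 32501 in the RefSeq table.

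Counts were analysed with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene lists. Genes were kept by edgeR's expression filter, which left 13891 of them. The smallest share of a library's counts held by the kept genes was 99.665%. Libraries were scaled by the TMM method, and factors ran from 0.97 to 1.05. A quasi-likelihood model with the 4 groups was fitted to all 16 libraries, and the 6 pairwise differences were tested with Benjamini-Hochberg adjustment within each comparison at a threshold of 0.05. All adjusted p-values of genes in the text come from this edgeR test. Standard errors are the log2 fold change divided by the square root of its F statistic. Levels are CPM, counts divided by the scaled library size, as mean ± SD over 4 libraries. A gene was counted as highest at an intermediate level when it was called higher in the low or the medium gate than in the negative gate and also called higher there than in the high gate.

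The 30 gene lists, with 438 genes, the comparisons, the tests and the rule for the genes to be named were set before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with fry and with the replicate number in the model. Some genes stand in more than 1 list: Cer1, Chrd, Foxj1, Msx1, Msx2, Nodal, Nog and Wnt6. For each comparison, the named genes had an adjusted p under the threshold, the same sign in all 4 same-numbered comparisons and a mean of at least 20 CPM in the higher group. Among these, the genes with the largest fitted change were taken, 12 in each direction for high versus negative, 6 for medium and low versus negative and 4 for the neighbouring gates, with 6 genes highest at an intermediate level by p. Unnamed gene models (Gm numbers, Rik) were not taken by this rule. Up to 4 members of each list described, and a fixed set of genes of the floor plate, Hedgehog and BMP pathways, were added whatever their result. Some genes that this rule takes are not reported here.

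Totals ran from 3268948 to 9961032 counts per library, so that 1 count was worth 0.306 CPM in the shallowest library and 0.1 CPM in the deepest. A count of 0 allows up to 3 counts, or 0.918 CPM in the shallowest library, from counting error only. Pairs of libraries within a group were compared by chi-square, and the smallest value per degree of freedom over 24 pairs was 4.25, so no library was counted as a duplicate. The steps were tested on simulated data, with counts drawn from the real means, library sizes and gene-wise dispersions. For high versus negative, 65 of 100 genes changed 2-fold and 95 of 100 changed 4-fold were recovered, with 12 false calls among 13691 unchanged genes. For high versus medium the numbers were 56 of 100 and 88 of 100, with 9 false calls.

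The alternatives were RLE scaling, DESeq2 1.42.0, no filter on low counts, the replicate number as a block, thinning of every library to the smallest total, each library left out in turn and a fit of only the 2 groups compared. A fit without the low 1 and medium 2 libraries, and a test of the floor plate list without Foxa2, were added after the data were seen.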

Results

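The data were 16 bulk 3′ RNA-seq libraries of cells from day 4 mouse neural tube organoids, grouped by the level of FOXA2, the transcription factor that marks the floor plate, the ventral midline of the neural tube. Each of the negative, low, medium and high gates had 4 libraries. Totals ran from 5451076 to 9961032 counts in the negative gate, from 5527287 to 7930805 in the low gate, from 5155331 to 7017046 in the medium gate and from 3268948 to 6517958 in the high gate. The share of counts on the 13 mitochondrial genes averaged between 1.88% and 2.05% in the gates. The first principal component held 28.8% of the variance and ordered the gates by FOXA2 level. The low 1 and medium 2 libraries stood apart from the others of their gates on PC3, which held 9.01%. Negative 3 also lay above its gate there (18.21, against at most 1.741). On PC2, which held 9.94%, high 2 lay at 36.52 and the other high libraries at 11.34 or less.

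**Figure D1:**
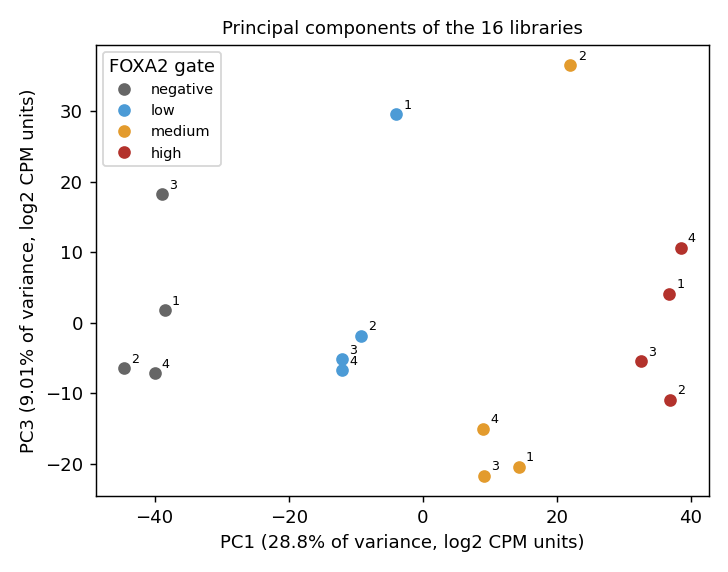
Scores of the 16 libraries on PC1 (horizontal) and PC3 (vertical), principal components of log2 CPM, coloured by FOXA2 gate and marked with the replicate number. The gates follow each other along PC1 (28.8% of variance), and low 1 and medium 2 lie highest on PC3 (9.01%).

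Foxa2 was examined first, because it checks the labels. The gene lies on chromosome 2 at 148042877 to 148046969 on the minus strand (GRCm38). Its level was 2.91 ± 1.68 CPM in the negative gate, 11.9 ± 3.02 in the low gate, 52.0 ± 9.36 in the medium gate and 113 ± 18.2 in the high gate (SD, n = 4). The log2 fold change of high versus negative was 5.36 (SE 0.263, adjusted p = 1.02e-12). Foxa2 defined the gates, so its rise is not a finding about them.

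The comparison of high with negative asked how cells with the most FOXA2 differed from those without it. Genes of the floor plate and its neighbours were higher in the high gate. Foxa1, a paralogue of Foxa2, went from 0.3 ± 0.272 to 9.23 ± 1.3 CPM, Spon1 (a secreted floor plate protein) from 9.01 ± 2.27 to 28.4 ± 1.94, and Ntn1 (the axon guidance cue netrin 1) from 11.8 ± 1.63 to 28.2 ± 5.57. Of 10 tested floor plate genes other than Foxa2, 7 rose and 0 fell, or 8 and 0 adjusted over the list alone (camera adjusted p = 3.74e-07). Foxa2 was left out of this count after the data were seen, because it set the gates; the list as fixed, with Foxa2, had 8 of 11 genes higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 5.47e-13). The ventral homeobox gene Nkx2-9 rose from 17.6 ± 3.97 to 168 ± 38.8 CPM and Nkx6-1 from 1.36 ± 0.839 to 15.4 ± 8.98. Of 4 tested ventral progenitor genes, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.00378). Shh, the ventralizing signal, was too low to be tested, with 26 counts in total over the 4 high libraries and 7 over the 4 negative ones.

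**Figure D2:**
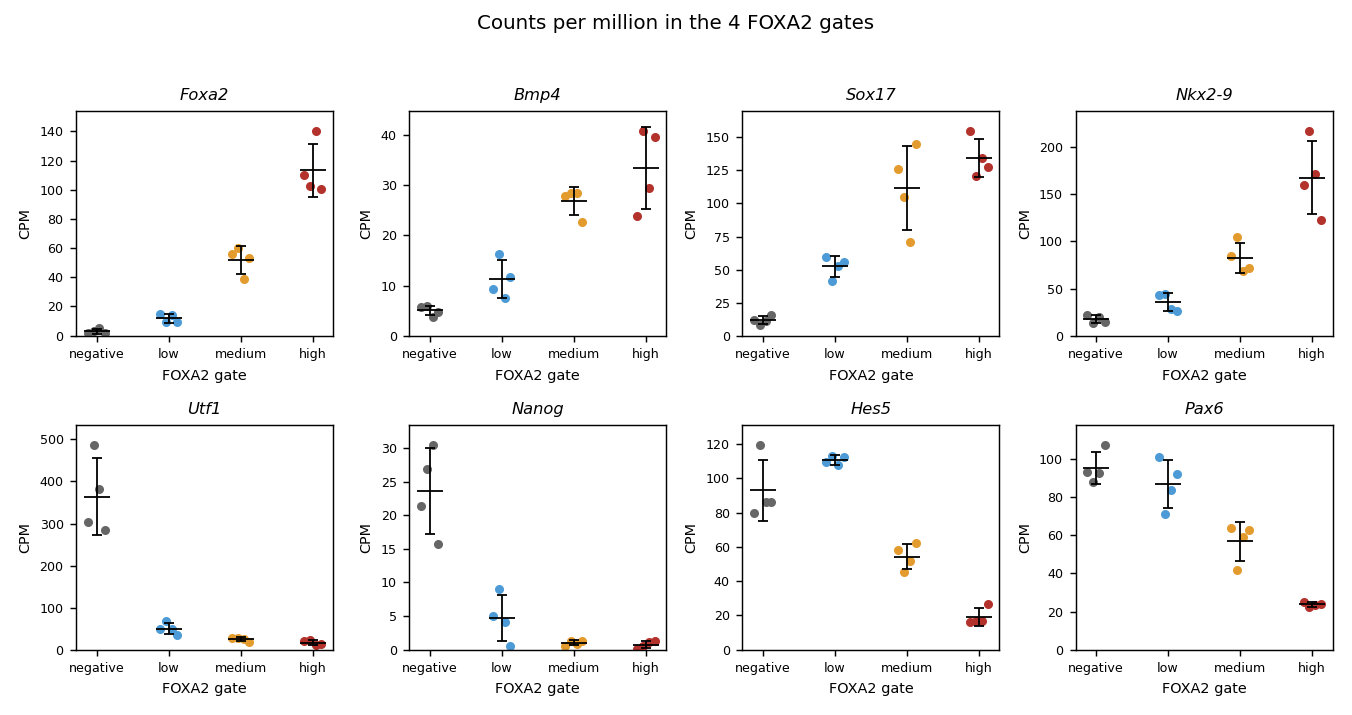
CPM (vertical axis) of 8 genes in the 4 FOXA2 gates (horizontal axis); points are libraries, and the bar with whiskers is the mean ± SD of 4. Foxa2, Bmp4, Sox17 and Nkx2-9 have their highest means in the high gate, Utf1 and Nanog are highest in the negative gate, and Hes5 and Pax6 are lowest in the high gate.

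Among the genes with the largest rises in the high gate were Vtn (vitronectin, a matrix protein; log2 fold change 5.06, SE 0.331, adjusted p = 1.45e-12), Igf1 (a growth factor; 4.71, SE 0.273, adjusted p = 1.55e-13) and Ntng1 (a netrin-related membrane protein; 4.39, SE 0.252, adjusted p = 1.55e-13). Kif26b, Arg1, Smoc2, Sp5, Hsd11b2 and Khdc3 followed, with log2 fold changes from 3.85 for Kif26b to 3.05 for Khdc3. The largest falls included pluripotency-associated genes. Nanog fell from 23.6 ± 6.45 to 0.742 ± 0.492 CPM, Utf1 from 364 ± 92.0 to 16.8 ± 5.26, Tdh from 91.4 ± 31.8 to 5.06 ± 1.66 and L1td1 from 115 ± 39.3 to 7.93 ± 5.38. Mylpf, Gtsf1l, Calcoco2, Klf2 and Gdf3 also fell, by between 3.60 and 4.12 on the log2 scale. The call of LOC108168785 rested on a single library: its level was 839 CPM in negative 1 and at most 5.84 in the other negative libraries, and without negative 1 its log2 fold change was -0.61 (adjusted p = 0.36).

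Neural progenitor genes were lower in the high gate. Of 13 tested pan-neural genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 2.9e-12), among them Hes5, a Notch target (from 92.9 ± 17.8 to 19.0 ± 5.18 CPM), Nrcam, Ncam1 and Rfx4. Of 17 genes of the intermediate and dorsal neural tube, 13 fell and 0 rose (14 and 1 adjusted over the list alone, camera adjusted p = 3.21e-13). Pax6 fell from 95.4 ± 8.27 to 23.7 ± 1.24 CPM, and Pax3 from 33.8 ± 4.68 to 5.46 ± 3.02. Zic1 fell by 2.25 on the log2 scale (SE 0.219). Fgf15 and Hes3, both of early neural tissue, fell by 3.89 and 3.70 on the log2 scale. Of 14 tested Hox genes, 4 fell and 0 rose (5 and 0 adjusted over the list alone, camera adjusted p = 0.00555, and adjusted p = 0.157 with an estimated correlation), Hoxa2, Hoxb3, Hoxb7 and Hoxd3. Of 11 neuronal genes, 5 fell and 1 rose (5 and 2 adjusted over the list alone, camera adjusted p = 0.0322, and adjusted p = 0.157 with an estimated correlation), with Stmn2 and Tubb3 lower; after thinning of all libraries to the smallest total 0 rose.

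BMP genes moved in more than 1 direction. Bmp4, on chromosome 14 at 46383520 to 46390669, rose from 5.03 ± 0.955 CPM in the negative gate to 33.4 ± 8.16 in the high gate (log2 fold change 2.71, SE 0.227, adjusted p = 2.52e-10), and Bmp7 from 31.9 ± 5.7 to 73.2 ± 10.6. Gdf3, a ligand of the same family expressed in pluripotent cells, fell. The BMP ligand list also holds Bmp1, which encodes a protease. Of the list's 9 tested genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.116 with an estimated correlation), and 1 fell after thinning. Among 11 secreted BMP antagonists, 4 rose and 0 fell (4 and 0 adjusted over the list alone), without a call for the list (camera adjusted p = 0.122). Chrd (chordin) went from 0.823 ± 0.516 to 7.09 ± 2.54 CPM, and Nog (noggin) was not tested, with 26 counts over all 16 libraries. The list of 9 BMP response genes was not called (2 rose and 2 fell, or 4 and 2 adjusted over the list alone, camera adjusted p = 0.274). Atoh8 rose, Id2 and Msx2 fell, Id1 was 76.0 ± 11.1 and 78.5 ± 17.1 CPM (adjusted p = 0.936) and Id3 was 460 ± 82.5 and 412 ± 33.9 (adjusted p = 0.494). The count of 2 that rose became 1 without negative 1, negative 2, high 3 or high 4.

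Hedgehog pathway genes also differed. Ptch1, the receptor that is itself a target of the pathway, rose from 28.7 ± 3.62 to 117 ± 19.9 CPM and Hhip from 3.03 ± 2.7 to 13.2 ± 3.14, and 2 of 4 targets rose with 0 falling (3 and 0 adjusted over the list alone, camera adjusted p = 0.000732, and adjusted p = 0.0673 with an estimated correlation). Gli1 was 14.0 ± 5.71 and 19.8 ± 1.91 CPM and did not pass (adjusted p = 0.106), but passed without negative 1 (log2 fold change 0.80, adjusted p = 0.0116). Of 11 co-receptors and effectors, 4 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 0.00958, and adjusted p = 0.179 with an estimated correlation), and Boc fell from 44.8 ± 6.46 to 10.9 ± 2.86 CPM. The 1 that rose was not called without negative 2, negative 4, high 1, high 3 or high 4.

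In the WNT pathway, 4 of 10 response genes rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.00555). Sp5 rose from 10.2 ± 3.47 to 93.6 ± 15.1 CPM, and Lef1 fell from 42.5 ± 10.6 to 24.0 ± 3.54. Among 14 WNT ligands and modulators, 6 fell and 2 rose (8 and 3 adjusted over the list alone, camera adjusted p = 0.00604); the secreted antagonists Sfrp1, Sfrp2 and Sfrp5 fell, and Dkk3 rose from 2.98 ± 0.943 to 22.5 ± 5.47 CPM. Of 16 FGF response genes, 7 fell and 0 rose (7 and 1 adjusted over the list alone, camera adjusted p = 0.000217, and adjusted p = 0.0673 with an estimated correlation), among them Spry4 and Etv4. In the retinoic acid list 2 of 10 genes rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.799); Stra6 rose, and the binding proteins Crabp1 and Crabp2 fell, Crabp2 from 2260 ± 430 to 745 ± 92.6 CPM. In the Notch list 3 of 12 genes rose and 2 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.502), with Hes1 and Hey1 higher and Lfng lower. The 4 WNT response genes that rose became 2 without negative 1, high 1 or high 4 and after thinning. The 2 WNT ligands and modulators that rose became 1 without high 2 and after thinning. The 2 Notch genes that fell became 1 without negative 3, high 3 or high 4. With the replicate block 4 retinoic acid genes rose in place of 2.

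Markers of other cell types moved with the gates. Of 14 tested pluripotency and epiblast genes, 11 were lower in the high gate and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 1.21e-21). Of 13 endoderm genes, 5 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 2.56e-07): Sox17 rose from 11.7 ± 3.02 to 134 ± 14.5 CPM and Cldn6 from 32.3 ± 4.96 to 149 ± 8.61, Ttr was at 1 count in the negative gate and 10.9 ± 1.64 CPM in the high gate, and Apoe fell from 1930 ± 158 to 1210 ± 82.5. Of endoderm genes too low to be tested, Gata6 had 4 counts over the negative libraries and 44 over the high ones, Afp 2 and 29, Apoa1 12 and 15, and Hnf4a 2 and 0. Of 9 notochord and axial mesoderm genes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 4.58e-09), with Krt19 and Krt18 higher beside Vtn and Chrd, and 0 lower after thinning. Basement membrane genes rose in 6 of 15 cases, with 0 lower (6 and 0 adjusted over the list alone, camera adjusted p = 2.24e-06), and Col4a1 went from 20.8 ± 2.97 to 112 ± 5.01 CPM. In the cell cycle list 8 of 24 genes fell and 2 rose (9 and 3 adjusted over the list alone, camera adjusted p = 0.0481, and adjusted p = 0.364 with an estimated correlation); Ccnd2 fell from 709 ± 51.7 to 299 ± 46.8 CPM and Ccnd1 rose from 182 ± 17.2 to 263 ± 9.92. Camera's call of the cell cycle list was also lost with the replicate block. The 8 that fell became 5 without negative 1, negative 3, high 1, high 2 or high 3. The 2 that rose became 1 without negative 1, negative 4, high 2 or high 3.

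**Figure D3:**
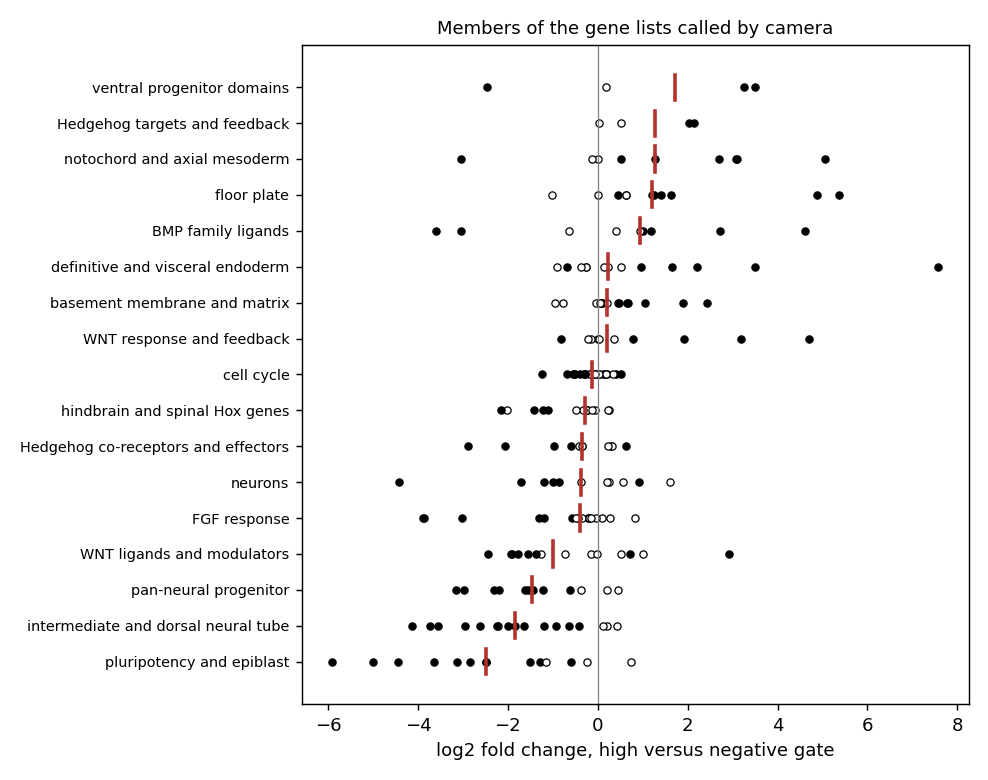
Fitted log2 fold change of high versus negative (horizontal axis) of each tested member of the 17 gene lists called by camera (rows); filled points passed the edgeR test, open points did not, and the red bar is the list's median, which for the floor plate list includes Foxa2, the gene that set the gates. The pluripotency list has the lowest median (-2.49) and the ventral progenitor list the highest (1.72); the fitted value of Ttr, farthest to the right, depends on the prior count because its negative libraries hold 1 count.

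In all, 1169 genes were higher and 1187 lower in the high gate than in the negative gate, of 13891 tested. Of 30 lists, camera called 17, and 10 of these calls held with an estimated correlation, the floor plate list with and without Foxa2 among them (adjusted p = 0.00791 without it). The mean level of 1487 of the 2356 called genes (63.1%) followed the order of the gates; 8.33% would do so by chance given the ends, although selecting genes for the difference between the ends does not leave the middle gates independent of it.

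Between medium and negative, the rise of Sox17 (log2 fold change 3.23, SE 0.203, adjusted p = 2e-10), Igf1, Ntng1, Arg1 and Khdc3 and the fall of Nanog, Tdh, Utf1, Klf2, L1td1 and Mylpf were the largest by the naming rule after Foxa2. Bmp4 was at 26.8 ± 2.8 CPM in the medium gate and Bmp7 at 74.0 ± 8.38, both called higher (adjusted p = 4.94e-09 and 1.31e-07), and Gdf3 and Nodal were lower. Of 14 pluripotency genes, 11 were lower and 0 higher (12 and 0 adjusted over the list alone, camera adjusted p = 4.57e-35). Of 13 endoderm genes, 6 were higher and 1 lower (6 and 1 adjusted over the list alone, camera adjusted p = 7.82e-08). Of 9 BMP response genes, 3 were higher and 1 lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.0327, and adjusted p = 0.128 with an estimated correlation), with Atoh8 and Msx1 higher. The 1 lower gene of this list was not called after thinning, with only the 2 groups in the fit, or without any 1 of negative 2, negative 3, low 3, low 4, medium 1, medium 3, medium 4, high 1, high 3 and high 4. With the replicate block 2 endoderm genes were lower. In total 589 genes were higher and 586 lower.

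Between low and negative, pluripotency genes were already lower in the low gate. Of 14 tested, 10 fell and 0 rose (13 and 0 adjusted over the list alone, camera adjusted p = 7.15e-41). Utf1 was at 50.0 ± 13.2 CPM in the low gate, Tdh at 8.71 ± 4.15, L1td1 at 14.3 ± 5.69, Klf2 at 2.97 ± 0.24, Calcoco2 at 3.77 ± 0.83 and Mylpf at 10.1 ± 4.29. Sox17 (log2 fold change 2.14, SE 0.202, adjusted p = 3.79e-07), Khdc3, Igfbp5, Pla2g7, Fndc5 and Meox1 had the largest rises by the naming rule. Of 10 floor plate genes other than Foxa2, Foxa1 and Slit1 rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00215, and adjusted p = 0.116 with an estimated correlation). With Foxa2 the list had 3 of 11 higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 1.06e-05, and adjusted p = 0.0317 with an estimated correlation). The call of Slit1 was lost without negative 2 (log2 fold change 0.71, adjusted p = 0.0603), without low 1 (0.71, adjusted p = 0.0523) and without low 4 (0.62, adjusted p = 0.0865). That of Foxa1 was lost after thinning (1.87, adjusted p = 0.132). Of 9 BMP response genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.00429, and adjusted p = 0.0832 with an estimated correlation). These were Msx1, which went from 62.0 ± 10.9 to 113 ± 15.6 CPM, and Bambi. The call of Bambi was lost without negative 1 (log2 fold change 0.69, adjusted p = 0.116), negative 2 (0.75, adjusted p = 0.0994), low 1 (0.76, adjusted p = 0.0899) or low 2 (0.71, adjusted p = 0.0969). It was also lost without low 1 and medium 2 (0.76, adjusted p = 0.0709) and after thinning (0.79, adjusted p = 0.144). Of 13 hypoxia and glycolysis genes, 2 fell and 0 rose (7 and 0 adjusted over the list alone, camera adjusted p = 0.000261, and adjusted p = 0.176 with an estimated correlation). They were Pdk1, which went from 38.2 ± 5.05 to 22.4 ± 3.42 CPM, and Aldoa. The call of Aldoa was lost without negative 2 (log2 fold change -0.39, adjusted p = 0.0956), low 1 (-0.45, adjusted p = 0.0582) or low 4 (-0.46, adjusted p = 0.0605) and without low 1 and medium 2 (-0.44, adjusted p = 0.0802). The count became 4 without negative 3 or low 2 and with no filter on low counts, and 5 with the replicate block. In the p53 list 2 of 14 genes rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0415, and adjusted p = 0.183 with an estimated correlation), Perp and Phlda3. This count became 0 without negative 2 (adjusted p = 0.105 for Perp and 0.192 for Phlda3), low 1 (0.0757 and 0.0919) or low 4 (0.0554 and 0.159). It became 1 without negative 1, negative 4, low 2, low 3, medium 1, medium 3, high 1 or high 4, with RLE scaling and after thinning. Of 13 endoderm genes, 4 rose and 1 fell (5 and 2 adjusted over the list alone, camera adjusted p = 0.00817, and adjusted p = 0.136 with an estimated correlation), and 2 fell with the replicate block. In total 204 genes were higher and 318 lower.

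The neighbouring gates differed in fewer genes. From low to medium, Igf1 rose by a log2 fold change of 2.24 (SE 0.233, adjusted p = 1.13e-06), Arg1 and Apela (a secreted peptide) by 1.35 each, and Fgf15, Hes3, Nr2f1 and Pax3 fell. The call of Pax3 was lost without low 1 and medium 2 (log2 fold change -1.05, adjusted p = 0.0966). Pan-neural genes were lower in the medium gate (2 of 13 fell and 0 rose, or 8 and 0 adjusted over the list alone, camera adjusted p = 2.49e-12), with Hes5 at 111 ± 2.66 CPM in the low gate and 54.4 ± 7.46 in the medium gate. The other called gene, Nrcam, lost its call without low 4 (log2 fold change -0.76, adjusted p = 0.0544), medium 2 (-0.71, adjusted p = 0.0609) or medium 3 (-0.70, adjusted p = 0.0795). The same held without low 1 and medium 2 (-0.69, adjusted p = 0.121) and after thinning (-0.74, adjusted p = 0.0512). Notochord genes were higher (3 of 9 rose and 0 fell, or 4 and 0 adjusted over the list alone, camera adjusted p = 1.59e-11), as were endoderm genes (4 of 13 rose and 0 fell, or 4 and 0 adjusted over the list alone, camera adjusted p = 1.98e-08; 2 rose with only the 2 groups in the fit) and Hedgehog targets (1 of 4 rose and 0 fell, or 2 and 0 adjusted over the list alone, camera adjusted p = 2.54e-05). The Hedgehog gene called, Ptch1, lost its call without low 3 (log2 fold change 0.92, adjusted p = 0.0519) and without low 1 and medium 2 (0.70, adjusted p = 0.0519). In total 68 genes were higher and 31 lower in the medium gate. Without low 3 the total of 99 became 54, and without medium 1 it became 57. It was 189 with no filter on low counts and 57 with only the 2 groups in the fit.

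From medium to high, Car4, Vtn, Dkk3 and Cobl rose, Cobl (an actin nucleator) from 21.3 ± 7.67 to 49.6 ± 7.16 CPM. Hes5 (log2 fold change -1.54, SE 0.158, adjusted p = 1.25e-06), Folr1 (a folate receptor), Sfrp5 and Kirrel3 fell. Of 13 pan-neural genes, 5 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 2.13e-17). The 5 became 3 without negative 3, negative 4, low 3, medium 4, high 1 or high 3, after thinning and with only the 2 groups in the fit. Of 17 intermediate and dorsal genes, 5 fell and 0 rose (10 and 0 adjusted over the list alone, camera adjusted p = 4.08e-17), Pax6, Zic1 and Pax7 among them. Of 14 WNT ligands and modulators, 2 fell and 1 rose (4 and 1 adjusted over the list alone, camera adjusted p = 1.46e-06), and Krt19 rose among notochord genes (2 of 9 rose and 0 fell, or 3 and 1 adjusted over the list alone, camera adjusted p = 0.000942, and adjusted p = 0.0714 with an estimated correlation). In total 51 genes were higher and 76 lower in the high gate, against 171 higher and 153 lower without low 1 and medium 2, a fit chosen after the data were seen. The total of 127 became 233 without medium 2, 81 without medium 3, medium 4 or high 2, 76 without high 1 and 222 with no filter on low counts. Between high and low, 527 genes were higher and 428 lower.

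Over all 4 gates, 1907 genes changed. Levels of 22 genes were highest at an intermediate gate, 21 at the low gate and 8 at the medium gate, 7 of them at both. Igfbpl1 was at 34.8 ± 1.38, 68.4 ± 9.02, 68.2 ± 17.7 and 36.9 ± 3.07 CPM from the negative to the high gate. Meox1, a homeobox gene best known from somites, was at 15.5 ± 1.39, 42.2 ± 3.29, 42.8 ± 6.19 and 23.4 ± 4.52, and Kirrel3, an adhesion protein, at 13.3 ± 3.06, 26.2 ± 4.84, 23.4 ± 3.17 and 8.93 ± 0.884. Fhod3 and Zdhhc15 were highest at the low gate and Lancl1 at the medium gate, by separate calls against the negative and the high gate. In a joint test of both differences, chosen after the results were seen, Igfbpl1, Meox1 and Kirrel3 passed. Fhod3, Zdhhc15 and Lancl1 did not pass it. Another grouping of the same libraries gave 64 genes by the same separate calls. The total of 22 became 38 without medium 2, 34 with the replicate block and 46 with no filter on low counts.

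**Figure D4:**
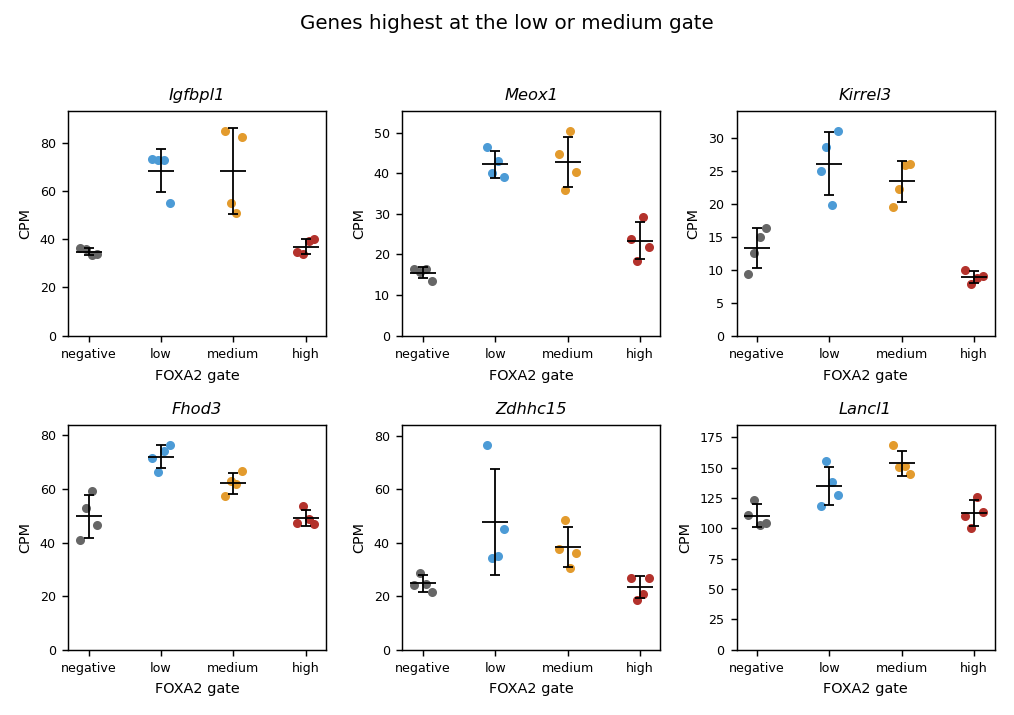
CPM (vertical axis) of 6 genes in the 4 FOXA2 gates (horizontal axis); points are libraries, and the bar with whiskers is the mean ± SD of 4. Igfbpl1 averages 68.4 CPM in the low gate, against 34.8 in the negative and 36.9 in the high gate.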

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

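The tests of the 3 patterns in this part were all chosen after the results were seen. In 25 of 536 groups of 4 libraries (134 quantities in 4 gates), 1 library lay far from the other 3, by the ratio of its gap to the whole range; chance gives about 1 in 20, and the share found was 4.66%. High 4 and medium 2 were the library in question 5 times each. Ratios for high 4 were 0.962 for Mylpf, 0.911 for Klf2, 0.864 for Igfbp5, 0.933 for Hes5 and 0.861 for Ntn1. For medium 2 they were 0.864 for Ptch1, 0.853 for Id3, 0.875 for Fgf17, 0.861 for Crabp2 and 0.858 for Pax7. For medium 4 they were 0.848 for Vtn, 0.834 for Utf1 and 0.88 for Bmp4. For high 2 they were 0.877 for Fndc5, 0.908 for Bmp7 and 0.968 for Slit1. For negative 1 they were 0.91 for LOC108168785, 0.904 for Gli3 and 0.946 for Pax7. For negative 2 they were 1 for Ttr, which rests on 1 count, 0.885 for Ccng1 and 0.84 for Cdkn1a. For low 2 they were 0.899 for Car4 and 0.939 for Etv4, and for low 4 the ratio was 0.976 for Igfbpl1.

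Pluripotency genes were higher in the negative gate, where 11 of 14 exceeded the high gate. Utf1 was at 364 CPM and Dppa5a at 114 CPM there. Of members too low to be tested, Fgf4 had 98 of its 105 counts and Pou5f1 64 of its 78 in negative libraries. Utf1 had 11814 counts over all libraries, so Fgf4 and Pou5f1 were low even in the negative gate, and their shares say little of their level. With all libraries thinned to the smallest total the list's median log2 fold change of low versus negative was -2.09 (13 genes tested, camera adjusted p = 1.08e-45). Totals of the negative gate (5451076 to 9961032 counts) and the low gate (5527287 to 7930805) overlapped, so thinning was a weak test of depth between them. The fall from negative to low arose at similar totals, which argues against depth for that comparison only. Totals of the high gate were lower (3268948 to 6517958). No thinned value of the list is given here for high versus negative, so depth is not decided there. Undifferentiated cells in the negative gate are a candidate source. That 10 of 14 genes were called lower in the low gate and 0 higher is part of the pattern itself, so it adds no separate support. The genes also varied together between libraries of a gate, with a mean pairwise correlation across genes of 0.303. The 95th percentile of 10000 random lists was 0.0619. Those lists were matched only on the mean log2 CPM over all libraries, not on differences between gates or on shared function. A list of related genes may exceed them for that reason alone, so the comparison does not decide the source. A lower level in every FOXA2-positive cell under 1 shared control would also make these genes vary together, and bulk libraries do not separate it from a share of cells.

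Of 13 tested endoderm genes, 5 were higher in the high gate and 6 in the medium gate than in the negative gate, while the call of the list for the low gate was lost with an estimated correlation (adjusted p = 0.136). Depth is argued against, since 5 members were still called higher in the high gate after thinning. Endoderm cells, which express FOXA2 themselves and so would not be removed by the gates, stay open as a source. The list's median log2 fold change lay 3.27 below that of Sox17, more than its SD of 2.32 (2.98 and 2.39 over all 17 members without a filter on low counts). Sox17 is a member with a large rise, so a wide gap to its own list's median follows from that choice and decides nothing. Of the 4 members that the filter had left out, 2 were called higher without it by edgeR, Gata6 (4 counts in negative and 44 in high libraries, adjusted p = 0.00119) and Afp (2 and 29, adjusted p = 0.00253), both named after their values were seen. Expression of Sox17, Cldn6 and Ttr in the organoids' FOXA2-positive neural cells may also be the source, and in bulk libraries it cannot be told apart from a share of endoderm cells.

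The 22 genes highest at an intermediate gate cannot come from a mix of negative and high cells alone if their level there exceeds both ends. In a 1-sided intersection-union test over both gates, 4 genes passed (Igfbpl1, Meox1, Kirrel3 and 1700011H14Rik, the last named after its values were seen), fewer than the 5 set as the bound, so for the other genes mixing and a true maximum cannot be told apart. The low 1 and medium 2 libraries are argued against, since 18 of the 22 genes were found again without them. Dilution of the negative gate by undifferentiated cells cannot be told apart from a rise of these genes: their median log2 fold change from negative to low was 0.691 above that of the pan-neural list (SD 0.391), and 0.579 to 1 above it for genes chosen on 2 libraries of each gate and measured on the other 2 (6 splits, 2 to 11 genes), but the pan-neural list itself was lower in the high than in the low gate (median -1.42), and such a fall could hide a rise from dilution. A response to an intermediate FOXA2 level stays open as a hypothesis.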

How the results depend on the processing

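The fit without low 1 and medium 2 and the floor plate list less Foxa2 were chosen after the data were seen. The 8 counts of genes and the Foxa2 change stayed within 1.5 times or kept their call with RLE scaling, with DESeq2 and after thinning. Without a filter on low counts, medium versus low called 189 genes, high versus medium 222, and 46 genes were highest at an intermediate gate. With only the 2 groups in the fit, medium versus low called 57. Without low 1 and medium 2, high versus medium called 324 genes (171 higher and 153 lower). With 1 library left out, medium versus low called 54 to 111 genes, high versus medium 76 to 233, and genes highest at an intermediate gate numbered 15 to 38. The cause of these shifts was not tested. Foxa2 stayed between 5.10 and 5.78 when 1 library was left out. The labels do not say that a number marks a shared culture, and the numbers were not taken to pair the libraries because 6 of 24 correlations between deviations of same-numbered libraries, not all, were above 0.1 (range -0.082 to 0.216). Their mean was 0.043 against -0.014 for other pairs. Of the pairs between gates, 24 shared a number and 72 did not, yet 11 of 16 libraries correlated best with their own number. That favours some shared origin of same-numbered libraries, which the main model leaves out. With the replicate block, high versus negative called 2468 genes and 34 genes were highest at an intermediate gate. Of 88 calls of lists over the 6 comparisons, 39 were kept with an estimated correlation. Without Foxa2 the floor plate list kept its call in the 6 comparisons (adjusted p from 3.74e-07 to 0.0375), but with an estimated correlation it was not called for low versus negative (adjusted p = 0.116) or high versus medium (0.256, and 0.0714 with Foxa2). With fry, which does not compare a list with other genes, 86 lists were called and 73 of the 88 calls were kept (8 lists against 15 for medium versus low, 7 against 12 for high versus medium); BMP antagonists (adjusted p = 0.0024) and BMP response genes (0.0255) were called for high versus negative. With the replicate block camera called 94 and kept 87, losing the cell cycle list for high versus negative (adjusted p = 0.0644). Of 203 results for named genes, 181 were called, 19 lost the call under at least 1 alternative and 0 reversed. Of 199 counts of called list members, 80 moved by over 1.5 times when 1 library was left out. Leaving out 1 library ended a named gene's call in 17, among them Nbl1, Bambi, Nkd1, Id2, Slit1, Aldoa, Perp, Phlda3, Nrcam, Krt18, Epcam, Fabp7 and Gli3. Depth limits genes such as Shh, and genes changed 2-fold were recovered less often than those changed 4-fold in simulated data.

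Chance is argued against for the 6 pairwise counts: of 35 splits of the 8 libraries, only the real one reached its own count. A share of 1 in 35 is the smallest that such splits can give, so they cannot exclude chance. Every other split also mixed libraries of both gates within a group, so a true difference between the gates widens its spread and lowers its calls. The low counts of the other splits are therefore no measure of how many calls chance alone would give. The highest other split called 2 genes against 2356 for high versus negative, 10 against 1175 for medium versus negative, 2 against 522 for low versus negative, 10 against 99 for medium versus low, 1 against 127 for high versus medium and 1 against 955 for high versus low. For any of the 4 gates, 1 of 100 groupings, the real one, reached 1907, and the highest other was 164. For genes highest at an intermediate gate, 2 of 100 groupings reached 22; the other gave 64, so a grouping of the same libraries in another arrangement can give more such genes than the real one.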

Other observations

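The other lists, tested for high versus negative, were not called. In the list of BMP receptors and SMADs 2 of 12 genes rose and 0 fell (2 and 0 adjusted over the list alone, camera adjusted p = 0.122). Of 5 forebrain and midbrain genes 1 fell and 0 rose (2 and 0 adjusted over the list alone, camera adjusted p = 0.364). In paraxial and lateral mesoderm 2 of 7 rose and 1 fell (camera adjusted p = 0.948), in neural crest and placode 2 of 9 rose and 2 fell (camera adjusted p = 0.282, upward although the median was -0.20), and in surface ectoderm 3 of 7 rose and 2 fell (camera adjusted p = 0.528). Of 14 p53 targets 4 rose and 0 fell (camera adjusted p = 0.265), of 18 adhesion genes 2 rose and 2 fell (camera adjusted p = 0.687), of 11 immediate early and heat shock genes 1 rose and 2 fell (camera adjusted p = 0.607), and of 13 hypoxia and glycolysis genes 1 rose and 0 fell (camera adjusted p = 0.545). In these 7 lists the counts adjusted over the list alone were equal to those over all genes. Leaving out 1 library moved several of these counts. The 4 p53 targets became 1 without negative 2 and 2 without high 1 or high 3. The 2 receptors and SMADs became 1 without high 3, and the 1 hypoxia gene became 0 without high 4. The 2 mesoderm genes that rose became 0 without high 3 and 1 without negative 2, negative 3, negative 4, high 1 or high 4 (2 fell without high 4). The 2 adhesion genes that rose became 1 without negative 3, negative 4 or high 2. The 2 surface ectoderm genes that fell became 1 without any 1 of 11 libraries (those other than low 2, low 4, medium 1, medium 2 and medium 3). The 1 forebrain and midbrain gene became 0 with DESeq2, after thinning and without any 1 of 10 libraries (those other than negative 4, low 1, low 2, low 3, medium 2 and high 4), and 2 without low 2. The median of the adhesion list was 0.10, although its test pointed downward.

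A noncoding RNA next to Foxa2, 9030622O22Rik, was singled out after its values were seen. It lies on chromosome 2 at 147944740 to 148040203 on the minus strand, 2674 bp from Foxa2 on the same strand. Its mean level was 0.409 ± 0.235, 0.947 ± 0.639, 8.92 ± 3.85 and 46.2 ± 3.16 CPM (SD, n = 4) from the negative to the high gate, with a log2 fold change of 6.88 for high versus negative (SE 0.45, edgeR adjusted p = 1.14e-10).

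Of the genes in the fixed lists, 12 were listed at 0 in every library, including Sox2, Sox1, Olig2, Hoxa4, Hoxa5, Hoxb4 and Hoxd4. Of these 12, 6 overlapped another gene on the same strand in GENCODE M21 (50%), against 55 of 340 tested list genes (16.2%; 2-sided Fisher's exact test p = 0.00844, over genes, which are not independent replicates). Sox2 lies within Sox2ot. Olig2 and Hoxb4 had no such overlap, so overlap does not cover all of them. For a gene with such an overlap, a listed 0 is no evidence that it was not expressed. For those without one, no fault of the counting was shown, and absence and a missed signal cannot be told apart.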
